A study of Harpegnathos saltator with 23 samples.

How the data were processed

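Brains without optic lobes were dissected from Harpegnathos saltator ants 1 day after injection of 100 ng of peptide, and poly(A) RNA was sequenced with a strand-specific dUTP protocol, per the labels' protocols. The labels put 11 libraries in the control group, which received a scrambled peptide, and 12 in the corazonin group. The labels name 4 flow cells, called runs A to D here. Run A held 2 control and 2 corazonin libraries, run B held 1 and 1, run C held 3 and 3, and run D held 5 and 6. The submitters' library ID prefixes followed the groups in run A, where control and corazonin libraries had different prefixes, and in part in run D, where 3 corazonin libraries had a prefix that no control of that run had. The labels do not say that each library came from a separate ant. The p-values set differences against the spread between these libraries and treat those of a run as independent. Ants were kept in nest groups of 6, and no fit had a term for nest group.

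The deposited expression table gives RPKM (reads scaled by gene length and by the reads of the library) for 19198 rows, made up of 18429 gene rows, 542 tRNA, 151 miRNA, 43 rRNA and 33 snRNA rows, per the file headers and row IDs. The submitters' processing notes name STAR 2.5.0b and DESeq2. The genome build, the annotation and the read counter are not given in the sources used here. The authors' deposited comparison has 18429 gene rows. Its columns are a mean signal over libraries, a log2 fold change of corazonin against control, a p-value and an adjusted p-value, per the file headers. A p-value is given for 16615 of the rows. Its model terms are not given in the sources used here. Columns were paired with samples by their names and the labels.

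The RPKM values allowed the reads behind them to be recovered. A value equals a whole number of reads divided by the gene's length and the library's total, and 280015 of 280015 values above 0 came out whole within 0.0001 reads. The recovered total of each library was the reads on gene rows, with the rRNA, tRNA, snRNA and miRNA rows left out of it, so a change in ribosomal RNA does not move the RPKM of other rows. In simulated data drawn for 15930 rows in 23 libraries, 99.9976% of the 291263 values above 0 gave back the simulated reads. Gene reads per library ran from 4665875 to 14567973. PCR reads without molecular identifiers are not independent molecules, so read numbers describe counting depth only. No 2 libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom over genes being 14.6, so no library was treated as a repeat deposit of another. That check does not show that libraries came from separate ants.

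Rows with a mean of at least 1 RPKM over the 23 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with run as a term, eBayes with trend and robust settings, and Benjamini-Hochberg adjustment at 0.05. Of the 10225 rows tested, 10146 were gene rows and the rest tRNA, rRNA, snRNA or miRNA rows. Counts of genes tested or called include these unless gene rows alone are named. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values. The group by run interaction was tested with limma's F test over runs A, C and D, which hold at least 2 libraries per group. In simulated data for the group comparison over 10225 genes, the fit recovered 88 of 100 genes changed by 1 on the log2 scale and 98 of 100 changed by 2, with 10 unchanged genes called. For the interaction over 10225 genes, 152 of 200 genes changed by 2 on the log2 scale in run D were recovered, with 7 unchanged genes called. Both simulations used the run means and gene spreads of the data, 200 changed genes and noise drawn independently for each gene. They do not show what would be recovered with correlated genes or with fewer changed genes. Single values were compared with a two-sided permutation test of the run-adjusted difference, with group labels permuted within run over 100000 resamples, and Benjamini-Hochberg adjustment over 5 values, which were both genes taken from the authors' deposited comparison, rRNA reads, snRNA reads and the trend with gene length. For the 2 genes picked by their limma p-value this test would repeat the selection, so they are left out of the adjustment and their p-values are not given. The 2 genes from the authors' deposited comparison were also picked from an analysis that rests on these libraries at least in part. Their permutation p-values therefore repeat that selection in part and describe the libraries only. In 300 simulated draws without a difference 4.67% had a p under 0.05, and in 300 with a shift of 2 SD 98.7% did. Classes of RNA with at least 5 tested rows were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used for the other steps.

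The design, the alternatives and 30 gene lists were set before the data were examined. The reference gene table given for this species (assembly Hsal_v8.6) shared 0 IDs with the expression table, and the files do not pair their IDs with gene names. The planned tests of vitellogenin, of the corazonin precursor and receptor and of the 30 gene lists were therefore not run. The rule for named genes took genes past the threshold that have a name, with at most 2 unnamed IDs in each direction. No gene passed and none has a name, so the 4 genes given by ID were chosen after their values were seen: both genes past the adjusted threshold in the authors' deposited comparison, and the gene row with the smallest limma p-value in each direction. The RNA classes, read from the row IDs, were also chosen after the data were seen. The alternatives varied the pseudocount, the filter, the scaling, the run and prefix terms, the replicate block, the libraries and runs included, and limma's variance and weight settings. Alternatives added after the data were seen were voom on the recovered reads, removal of each library's trend with gene length, gene rows alone, and the checks of the RNA classes and of the permutation tests.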

Results

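Harpegnathos saltator is a ponerine ant whose workers can become egg layers after dueling tournaments. Ants that had dueled for 3 consecutive days were taken on day 6 of this transition, moved to a nest in groups of 6, and injected in the head. Of each group 3 received corazonin, an insect neuropeptide related to gonadotropin-releasing hormone, and 3 a scrambled control peptide. The data are 23 brain RNA-seq libraries made 1 day later, 11 from control and 12 from corazonin injections. Gene reads per library ran from 5214515 to 13587021 in the control group and from 4665875 to 14567973 in the corazonin group. Run A was the deepest, at 7775199 to 14567973 gene reads, and run D the shallowest, at 4665875 to 6686230.

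The libraries differed mainly by sequencing run. The first principal component of log2(RPKM + 1) held 57.3% of the variance and the second 12.0%. Run accounted for 80.8% of the spread along the first and 83.5% along the second, and injected peptide for 1.05% and 0.21%.

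**Figure D1:**
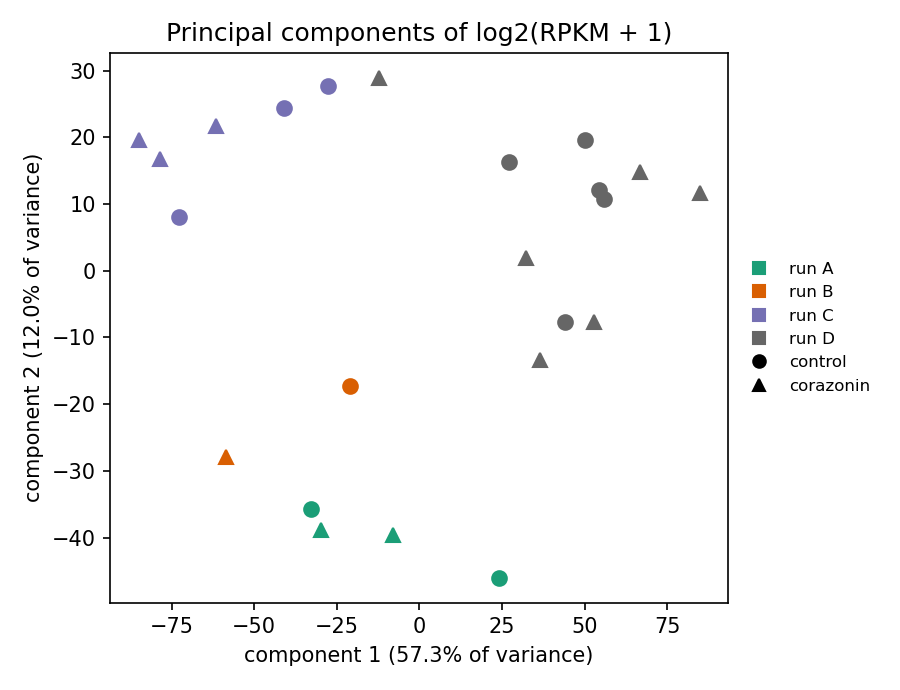
Principal components 1 and 2 of log2(RPKM + 1) over the 10225 rows tested, rRNA, snRNA, tRNA and miRNA rows included. Each point is 1 library, colored by run, with circles for control and triangles for corazonin. On component 1, run D libraries lie at 27.2 or above except corazonin replicate 10 at -12.1, and those of the other runs at -7.95 or below except control replicate 2 of run A at 24.1.

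The first comparison asked which brain transcripts differed after corazonin. Hsal_09096.2 had the largest ratio between group means of the 4 genes given here. It stood at 15.7 ± 29.7 RPKM in control brains (SD, n = 11; median 2.11) and 0.672 ± 0.911 RPKM in corazonin brains (SD, n = 12; median 0.364). The control mean was 23.3 times and the control median 5.79 times the corazonin value, and without control replicate 3 these ratios were 11.04 and 5.62. Controls ranged from 0.495 to 98.3 RPKM, and 5 of the 11 lay above every corazonin library, while 9 of the 12 corazonin libraries lay below every control. Controls held 6845 reads in all, at 17 to 3359 per library, against 374 in the corazonin libraries, at 1 to 149. Most of the control reads came from control replicates 3, 5 and 2, with 3359, 1501 and 1362. The corazonin mean was lower in each run, by log2 differences of -1.33 in run A, -6.11 in run B, -2.80 in run C and -0.82 in run D. Its limma fold change was -1.89 ± 0.52 (SE) with an adjusted p of 0.634, which did not pass. A within-run permutation test of this gene alone gave p = 0.00316, or 0.0079 adjusted over 5 tests. That p takes no account of the gene having been picked from the authors' deposited comparison, which rests on these libraries at least in part. Control replicate 3, the only control of run B, held 3359 of its reads, and without that library the fold change was -1.49.

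Hsal_09583 had the smallest limma p-value of the genes with a positive fold change. Its RPKM was 1.26 ± 0.32 in control brains (SD, n = 11) and 3.28 ± 1.36 in corazonin brains (SD, n = 12), a ratio of means of 2.60. Of the 12 corazonin libraries 10 lay above every control. The log2 difference was 0.46 in run A, -0.25 in run B, 1.05 in run C and 1.07 in run D. The limma fold change was 0.84 ± 0.16 (SE) with an adjusted p of 0.296. It passed the adjusted threshold without corazonin replicate 2 (limma adjusted p = 0.0366) and without run B (0.0435). It also passed without control replicate 3 (0.0438) or corazonin replicate 3 (0.0435), the only libraries of run B. With run as a term these are in effect the fit without run B, with the same fold change of 0.94. Over the 23 fits that leave out a library the adjusted p ranged from 0.0366 to 0.831.

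Hsal_00630, a gene of 305 bp, had the smallest limma p-value of those with a negative fold change. Its RPKM was 384 ± 113 in control brains (SD, n = 11) and 276 ± 56.0 in corazonin brains (SD, n = 12), a ratio of control to corazonin means of 1.39. The log2 difference was -0.57 in run A, -0.59 in run B, -0.35 in run C and -0.46 in run D. The limma fold change was -0.46 ± 0.12 (SE) with an adjusted p of 0.634, which did not pass.

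Hsal_04557 stood at 1.11 ± 0.68 RPKM in control brains (SD, n = 11; median 1.06) and 9.71 ± 19.4 RPKM in corazonin brains (SD, n = 12; median 1.56). The higher mean came from corazonin replicate 8, with 55.2 RPKM and 437 reads, and corazonin replicate 10, with 46.7 RPKM and 481 reads. Both were in run D, where the log2 difference was 1.93, against 0.24 in run A, 0.10 in run B and 0.06 in run C. The limma fold change was 0.99 ± 0.54 (SE) with an adjusted p of 0.634, the permutation p was 0.0695, and without run D the fold change was 0.13.

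**Figure D2:**
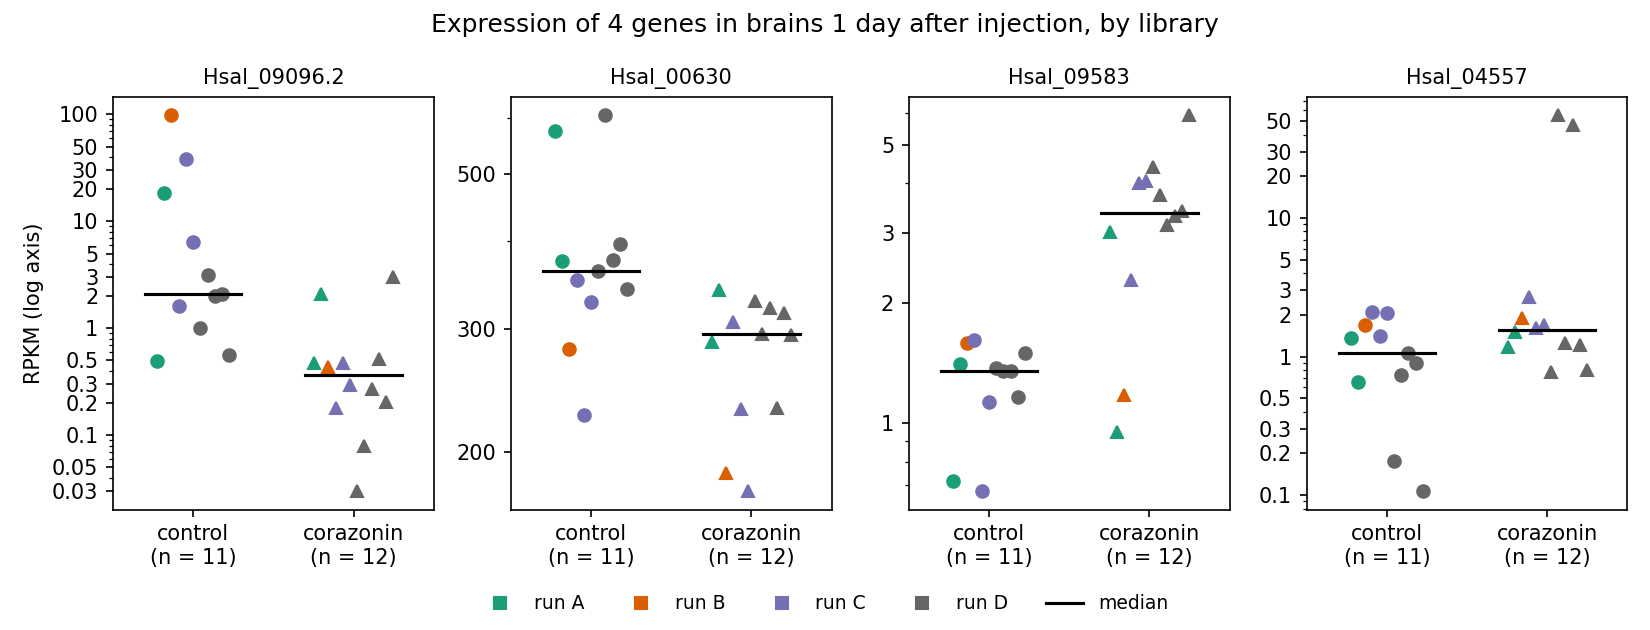
RPKM of 4 genes per library on log axes, 11 control (circles) and 12 corazonin (triangles) libraries, colored by run, with a line at each group's median. Hsal_09096.2 spreads from 0.495 to 98.3 RPKM in controls, 5 of which lie above every corazonin library, and Hsal_04557 is high in 2 corazonin libraries of run D.

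Across all 10225 rows tested with limma, 10146 of them gene rows, 0 passed the adjusted threshold, the smallest adjusted p being 0.296. With gene rows alone 0 passed as well, and 737 had an unadjusted p under 0.05. At an unadjusted p under 0.05 there were 750 genes, 334 higher and 416 lower in corazonin brains, and with libraries scaled by their median ratio the split was 450 higher and 314 lower. Voom on the recovered reads also called 0 genes, with 1039 at an unadjusted p under 0.05, or 2360 with library weights. The median log2 fold change was -0.02 and the median SE 0.15.

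The small nuclear RNAs take part in splicing and lack a poly(A) tail. Poly(A) RNA was sequenced, so their reads need not follow their level in the brain. As a class, chosen after the data were seen, they were lower in the corazonin libraries. All 13 tested snRNA rows had a negative fold change, with a median of -0.59. None passed the threshold over all genes and 2 did when adjusted over the list alone, both lower. Camera placed the class below other genes with an adjusted p of 1.28e-08 at the preset correlation of 0.01. The correlation estimated from the snRNA rows was higher, at 0.32, and with it the camera adjusted p was 0.0431. The preset value takes the rows as nearly independent, so a camera call kept at that value is a weak check. No run was left out at the estimated correlation, so whether the camera call at 0.32 depends on 1 run was not tested. Fry, which tests whether the rows move one way on balance and compares them with no other genes, gave an adjusted p of 0.0119. Summed snRNA reads per 1000000 gene reads were lower by a run-adjusted log2 difference of -0.73, with the corazonin mean lower in 4 of 4 runs (permutation p = 0.00153, or 0.00765 adjusted over 5 tests). Without run D the difference was -0.65 with a permutation p of 0.0494. The permutation p was 0.00285 without run A, 0.00354 without run B and 0.00948 without run C. In run D they were 996 ± 243 per 1000000 gene reads in controls (SD, n = 5) and 602 ± 234 in corazonin libraries (SD, n = 6). In run C they were 90.8 ± 48.3 (SD, n = 3) and 47.6 ± 14.8 (SD, n = 3). The gap was smaller in run A, at 109 ± 12.2 (SD, n = 2) and 96.4 ± 5.72 (SD, n = 2), a log2 difference of -0.17 against -1.01 in run B, -0.85 in run C and -0.81 in run D. Run B had 1 library per group, at 141 and 70.1.

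Ribosomal RNA, which also lacks a poly(A) tail, moved beside it in run D. There it took 4.54 ± 0.97% of all reads in controls (SD, n = 5) and 2.85 ± 1.15% in corazonin libraries (SD, n = 6), while libraries of runs A to C held 0.111% to 0.623%. Of the 32 tested rRNA rows 26 had a negative fold change, with a median of -0.32, and 1 passed when adjusted over the list alone. The camera call (adjusted p = 6.42e-05) was lost with an estimated correlation (adjusted p = 0.266), and without run D (adjusted p = 0.43). The run-adjusted difference in rRNA reads, -0.37 on the log2 scale, had a permutation p of 0.139 and was negative in 2 of 4 runs. The 25 tRNA rows (camera adjusted p = 0.501) and 9 miRNA rows (adjusted p = 0.735) gave no class call, with 1 tRNA row, higher, past the threshold when adjusted over the list alone.

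**Figure D3:**
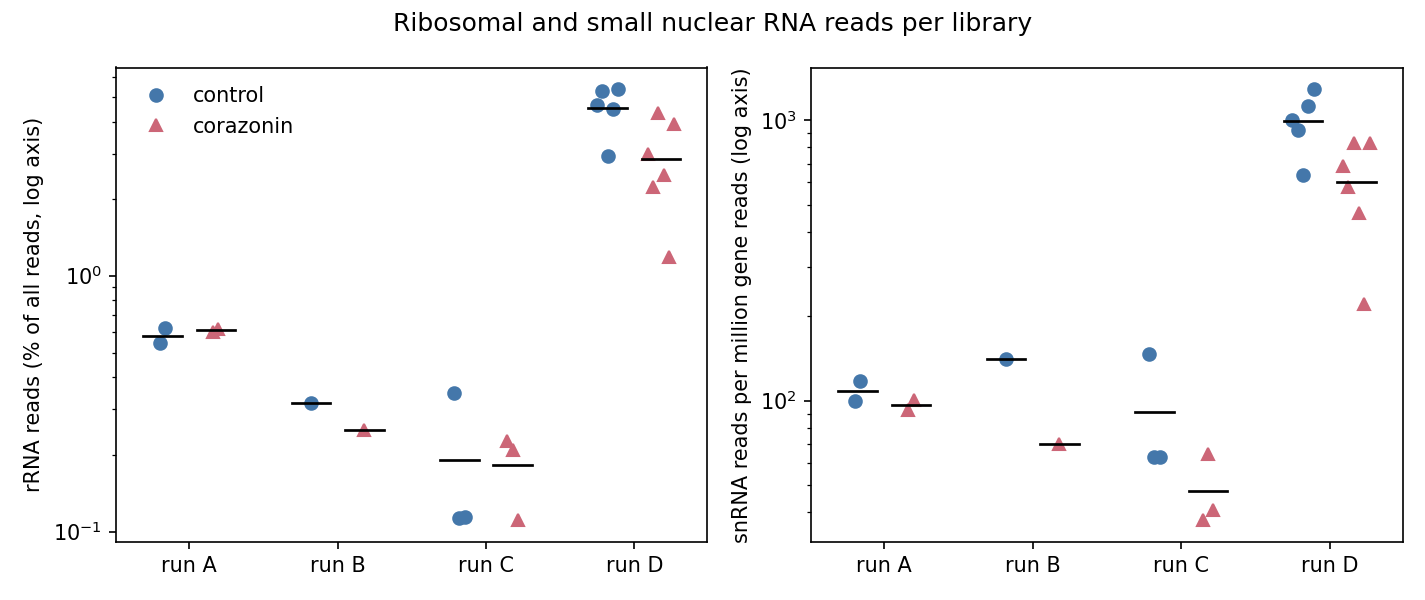
Ribosomal RNA reads as a percent of all reads (left) and snRNA reads per 1000000 gene reads (right), on log axes, per library by run, with circles for control, triangles for corazonin and a line at each mean. Run D lies far above the other runs in both, and the corazonin mean for snRNA is the lower one in 4 of 4 runs.

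The second comparison asked whether the corazonin effect differed between sequencing runs. Over 10225 genes and runs A, C and D, limma's interaction test called 0 genes, with 102 (0.998%) at an unadjusted p under 0.05. For Hsal_09096.2, Hsal_09583, Hsal_00630 and Hsal_04557 the interaction p-values were 0.194, 0.322, 0.853 and 0.306 by limma. Run B, with 1 library per group, could not enter the test. Its log2 differences for these genes were -6.11, -0.25, -0.59 and 0.10, so the test does not show that the effects were alike in all runs.

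The third comparison set these fold changes beside the authors' own. Of 16615 genes with a p-value in the authors' deposited table, 2 had an adjusted p under 0.05. Those were Hsal_09096.2, with a log2 fold change of -1.36 and an adjusted p of 0.0285 in the authors' deposited table, and Hsal_04557, with 1.87 and 0.0285. Neither passed in the limma fit. Its fold changes of -1.89 and 0.99 are on the log2(RPKM + 1) scale, and voom on the recovered reads gave -3.93 and 1.34. The authors' values come from another method, so the sizes are not like for like. Over 10146 genes, which are not independent replicates, the fold changes of the limma fit and of the authors' deposited table correlated with a Pearson r of 0.899 and a Spearman rho of 0.915, and 89.2% had the same sign. At an unadjusted p under 0.05 the limma fit had 734 of these genes, with 261 in the authors' deposited table and 179 in both, against 18.9 for independent lists. With no run term the limma fit had 133, of which 93 were in both, so the count depends on that term. Over all 16615 genes, 353 (2.12%) had an unadjusted p under 0.05 in the authors' deposited table. Both rest on the same libraries at least in part, so the overlap is not independent evidence.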

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

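The tests of carry-over in Hsal_09096.2, of its dependence on 1 library, of Hsal_04557 and of the snRNA class were set after the gene or class had been noticed, though before the outcome of each test was seen. The comparison of the authors' means with the recovered reads was chosen after the data were seen.

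The authors' deposited table gives a mean above 0 for 955 genes that are at 0 in all 23 columns of the RPKM table, the highest such mean being 0.724. Hsal_09096.2 has a mean of 2096 in the authors' deposited table against 314 reads per library here, a ratio of 6.68, where the median ratio over 9774 genes with at least 10 reads per library was 1.06 and 95% of them lay between 0.718 and 1.54. The ratio was 2.37 for Hsal_09583, 1.83 for Hsal_04557 and 1.13 for Hsal_00630. The cause of these differences was not tested.

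Hsal_09096.2 was lower after corazonin. Dependence on 1 library is argued against by the 23 fits that leave out a library, where the largest within-run permutation p was 0.00852. Leaving out a whole run gave p of 0.00249 (run A), 0.00671 (run B), 0.0422 (run C) and 0.0337 (run D) in the same test. The fits that leave out 1 library do not address dependence on a few control libraries together. Carry-over of another tissue into some control brains would bring other transcripts along, yet 39 genes followed Hsal_09096.2 across controls at a run-centred r of at least 0.8, against a median of 126.5 for 200 genes of like spread, and 19 of the 39 had a negative fold change. That test is blind to control replicate 3, which has no other control in its run, and to a tissue dominated by this transcript. It also takes for granted that the 200 genes do not themselves vary through carry-over. An effect of the peptide on this gene may remain as a hypothesis, found and tested on the same libraries.

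Hsal_04557 was high in corazonin replicates 8 and 10 alone. In these libraries 5 other genes were also at least 4-fold above the highest other run D library in both, against at most 1 in any of the 54 other pairs of run D libraries. Carry-over of another tissue in these 2 libraries could give this, and so could a shared response to the peptide, which was not tested. The rule set beforehand asked only for a count above all other pairs, so 5 genes meet it without showing carry-over. The files hold no gene names to tell these apart.

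The snRNA class was lower in the corazonin libraries. With the rRNA level as a term, the run-adjusted log2 difference went from -0.73 ± 0.22 (SE) to -0.46 ± 0.14 (SE), so 62.8% of it was left. Varying carry-over of RNA without a poly(A) tail may therefore account for part of it, and cannot be told apart from an effect of the peptide on the rest, since rRNA measures such carry-over only indirectly. Removing each library's trend with gene length left the class median at -0.60.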

How the results depend on the processing

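Library left-outs, runs, scalings, filters and pseudocounts were planned, and voom, the length trend, gene rows alone and the checks of RNA classes and permutation tests were added after the data were seen. The count of 0 genes called by limma held in 38 of 43 alternatives. It was 1 without the 3 run D corazonin libraries whose prefix no control of that run had (a tRNA row, adjusted p = 0.0285) and 1 without run B (Hsal_09583), and ranged from 0 to 1 over the 23 fits that leave out a library; the cause was not tested. Genes at an unadjusted p under 0.05 numbered 750, against 135 with no run term, 259 without run C, 391 without run B, 1316 with run and prefix as a term, 1631 without the 3 libraries, 1727 with array weights, 1731 without run D and 2360 by voom with library weights, and 390 to 1516 over the left-out libraries (fewest without corazonin replicate 3, most without corazonin replicate 9). The interaction count was 1 at a pseudocount of 0.1, 0 for runs C and D alone, and 0 to 1 over left-out libraries (1 without control replicate 6 or control replicate 11); the cause was not tested. The Pearson r with the authors' deposited table was 0.907 with no run term. Hsal_09096.2, Hsal_04557 and Hsal_00630 kept their direction and stayed above the adjusted threshold in 43 alternatives each, with adjusted p of at least 0.0984, and Hsal_09583 in 38 of 42. Fold changes of Hsal_09096.2 lay between -4.42 by voom with library weights and -1.49, and its permutation p stayed under 0.05 in 27 of 27 fits. The highest was 0.0422, without run C. All of these fits share the libraries from which the gene was picked, so they do not test it afresh. Leaving out run B or either of its libraries is in effect the same fit, so the limma and permutation counts hold repeats. The snRNA call held in 9 of 9 alternatives, only 1 at the estimated correlation. The rRNA call was lost in 4 of 9. The miRNA median, with no call, turned to 0.31 without run D, 0.0093 with median-ratio scaling and 0.11 with no run term. Same-numbered libraries correlated at -0.21 to 0.72 around group means (3 of 11 controls best with their own number, in runs A and B). Centred within run, 3 of 10 pairs exceeded 0.1, run A's pairs tied by centring, so pairing stays open. With the replicate block, which leaves out corazonin replicate 12 for want of a partner, 0 of 10221 genes were called, with 1108 at an unadjusted p under 0.05, and leaving out that library without the block gave 1113. Tests of vitellogenin and gene lists were not run for want of gene names. The planned raw count test was not run, since the deposited values are RPKM. Low depth limits genes near 1 read per library.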

Other observations

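The length test was added after the data were seen, and the split tests of the adjusted counts after those counts were seen.

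The 750 genes at an unadjusted p under 0.05 are more than the 5% that chance alone gives on average, but chance cannot be excluded. Of 100 splits of the 23 libraries within run, the real one included, 17 gave at least as many such genes, the highest other giving 3204 and the median other 228. A split with several times the real count may come from a structure of the samples or from correlation between genes, and neither was tested. Gene length bias between libraries is argued against as the whole cause, since removing each library's trend with gene length left 733 genes, of which 586 were among the 750.

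With a count of 0 the splits decide nothing, since every split gives at least as many. That holds for the genes past the adjusted threshold (100 of 100 splits, highest other 1) and for the interaction (100 of 100 splits, highest other 43).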
